A study of Mus musculus with 9 samples.

How the data were processed

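The samples are 9 liver samples of wild-type C57BL/6 mice, each sequenced as a poly(A)-selected, strand-marked RNA library read from both ends. All mice had received thioacetamide, a liver toxin that causes fibrosis, for 10 weeks. They fall into 3 groups of 3 libraries: saline controls (replicates 12, 13 and 14, called TAA here), recombinant human cytoglobin (rhCYGB) at 2 mg/kg during the last 2 weeks (replicates 17, 18 and 19), and rhCYGB at the same dose during the last 5 weeks (replicates 23, 27 and 28). Livers without thioacetamide are not among the samples, so no comparison with healthy liver was made. The groups share no replicate number, so nothing pairs the libraries. The labels number the samples within groups of mice without stating that each number is a separate mouse, so p-values measure the spread between these samples.

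The submitters' processing notes name FastQC 0.11.7, HISAT2 2.1.0, StringTie 1.3.4d and the mouse genome build mm10. The values used are estimated counts of reads per gene as deposited by the authors, per the file headers, after HISAT2 alignment and StringTie assembly according to those notes. They are whole numbers for 24532 genes with RefSeq annotation. In the matching table of 36780 transcripts, counts lie within 1 read of FPKM times transcript length times a constant for each library, rounded up, for 96.4%, 95.7% and 96.0% of transcripts in the TAA libraries. The step that made them from StringTie output is not stated. For 107 genes, all with transcripts at more than 1 locus, the gene count lies below the sum of its transcripts. The FPKM values made by the authors, per the file headers, served for an alternative only. How reads were counted by strand is not recorded, so antisense genes cannot be told from their partners, and members of near-identical families (glutathione transferases, major urinary proteins, Cyp2 and Cyp4a genes, serum amyloid and orosomucoid genes) are uncertain as single genes.

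Library totals ran from 55655727 to 87289945 estimated reads, a 1.57-fold range, with the deepest library replicate 18. The common biological coefficient of variation was 24.9%.

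Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14731 genes. Counts were scaled by TMM and tested with edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and calls at an adjusted p under 0.05. The 9 libraries entered a single fit with 3 groups (6 residual degrees of freedom), from which came rhCYGB 2 weeks against TAA, rhCYGB 5 weeks against TAA, and rhCYGB 5 weeks against rhCYGB 2 weeks. A second fit compared all 6 rhCYGB libraries with the 3 TAA libraries (any rhCYGB against TAA). Log2 fold changes are given with an approximate standard error (SE), the size of the change divided by the square root of its F statistic. Levels are given as TMM-scaled CPM with their standard deviation (SD). Scaling by library totals alone moved the median log2 change of all genes by -0.33, -0.22, 0.11 and -0.27 in the 4 comparisons in that order, and log2(FPKM + 1) moved it by -0.28, -0.20, 0.10 and -0.25. Directions are therefore relative to the TMM scale.

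Before the data were examined, 56 gene lists, a panel of 32 genes, the tests, most alternatives and the rule for named genes were fixed. Of 1182 list symbols, 1143 matched the table, and 53 lists had at least 5 tested genes. The lists were tested with limma 3.58.1: camera at a preset correlation of 0.01 as the main test, camera with an estimated correlation, and fry, each adjusted over the 53 lists. The rule named the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM and groups that do not overlap, the panel, and up to 4 called members (otherwise the member with the lowest p) of each list. Il6, a panel gene, was below the filter. No test result is given below for the panel genes Tgfb1, Pdgfrb, Lox, Des, Mmp2, Mmp13, Spp1, Krt19, Tnf and Il1b. The same holds for Adgre1, S100a8, Hmox1, Nqo1, Cybb, Alb, Cyp7a1, Cdkn1a and Afp. Of these genes, the 2-week libraries lay apart from TAA only for Mmp13, Cyp7a1 and Afp (lower) and Nqo1 (higher). The 5-week libraries did so only for Tgfb1, Pdgfrb, Des, Tnf, Cybb and Cdkn1a, all lower. Gene models without a proper symbol were left out of the named genes.

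The tests were tried first on simulated counts for the same design, with 100 genes changed 2-fold and 100 changed 4-fold. For rhCYGB 2 weeks against TAA (14584 genes), edgeR recovered 44% and 95% of these, with 5 false calls among 145. For rhCYGB 5 weeks against TAA (14608 genes) the values were 56%, 96% and 9 among 161, for 5 weeks against 2 weeks (14615 genes) 46%, 91% and 5 among 142, and for any rhCYGB (14608 genes) 60%, 99% and 10 among 171. These counts held no trend over gene length. With a length trend imposed on the simulated 2-week group (14581 genes), 1131 of 1308 calls were false (86.5%), and 8 of 157 once the trend was removed. A planted list was called each time and 0 of 50 random lists were. Genes were drawn independently there, so this does not test list calls where genes vary together. For any rhCYGB, splits of the real libraries other than the real one gave up to 36 called lists. The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), other tools (DESeq2 1.42.0, limma voom with sample weights, limma on log2(FPKM + 1)), other filters and thresholds, counts summed from transcripts, fewer libraries per fit, and each library left out in turn. After the data were examined 2 more were added: removal of each library's trend over gene length and GC content (splines with 5 degrees of freedom, 14551 genes or 98.8% with values), and leaving out replicates 17, 18 and 23 together. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.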

Results

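Whole-liver messenger RNA from wild-type mice given thioacetamide (TAA), which causes fibrosis, for 10 weeks was sequenced in 9 libraries, in 3 groups of 3. Controls received saline, and the other groups received recombinant human cytoglobin (rhCYGB), a globin protein, during the last 2 or the last 5 weeks. Each library held 55655727 to 87289945 estimated reads, and 14731 genes were tested. Expression of the mouse Cygb gene itself (gene ID 114886, mm10 chromosome 11, 116645595 to 116654313), which stellate cells express, spanned 19.4 to 29.0 CPM (TMM-scaled counts) in TAA, 14.1 to 21.2 after 2 weeks and 8.93 to 21.7 after 5 weeks (n = 3 each). The log2 changes of Cygb against TAA were -0.55 ± 0.32 (SE, adjusted p = 0.317) and -0.51 ± 0.32 (adjusted p = 0.415), the latter -0.21 without replicate 23, which had 8.93 CPM. The groups of libraries overlapped.

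Comparing rhCYGB 2 weeks against TAA asks what a short course of the protein did to the injured liver. Acta2, the smooth muscle actin of activated stellate cells (gene ID 11475, mm10 chromosome 19, 34240336 to 34255373), fell by 2.15 ± 0.42 on the log2 scale (SE, n = 3 per group), from 52.8 ± 21.3 CPM to 11.9 ± 5.45 CPM (SD, adjusted p = 0.0327). Col1a2, a chain of type I collagen (gene ID 12843, mm10 chromosome 6, 4505618 to 4541543), fell by 1.91 ± 0.42 (adjusted p = 0.0440), from 364 ± 81.9 to 96.6 ± 55.6 CPM. Mki67, a marker of dividing cells, fell by 0.98 ± 0.16 (adjusted p = 0.0240), from 56.3 ± 1.88 to 28.5 ± 5.86 CPM. The epoxide hydrolase Ephx1, a detoxification enzyme, rose 2.00-fold (log2 change 1.00 ± 0.12, adjusted p = 0.0154). The largest rise was that of Saa3, an acute phase serum amyloid (gene ID 20210, mm10 chromosome 7, 46711998 to 46715676), 44.3-fold from 5.62 ± 2.02 to 249 ± 188 CPM (log2 change 5.47 ± 0.82, adjusted p = 0.0240, and 4.75 without replicate 17).

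Collagen and matrix lists ranked lower at 2 weeks. Of 17 tested collagen genes, 7 fell, 1 rose and 9 were not called, and 13 fell and 2 rose when adjusted over the list alone. Their median log2 change was -1.02 (camera, adjusted p = 1.59e-10, and adjusted p = 0.217 with an estimated correlation). Col8a1 fell by 2.78 ± 0.35, Col5a2 by 1.92 ± 0.35, Col5a1 by 1.61 ± 0.28 and Col4a1 by 1.17 ± 0.22. Col1a1 stood at 96.3 ± 71.7 CPM against 359 ± 122 in TAA (log2 change -1.90 ± 0.56, adjusted p = 0.0853, with 179 CPM in replicate 18 against 62.1 and 48 in 17 and 19), and Col3a1 at 178 ± 75.7 against 583 ± 101 (-1.71 ± 0.40, adjusted p = 0.0507), so neither was called. Among 25 matrix glycoproteins and proteoglycans 6 fell and 19 were not called, and 9 fell and 1 rose when adjusted over the list alone. That list had a median of -0.55 (adjusted p = 2.85e-06, and 0.338 as adjusted p with an estimated correlation). It includes thrombospondins Thbs1, which fell by 1.91 ± 0.32, and Thbs2, by 1.21 ± 0.21, the microfibril protein Fbn1, by 1.48 ± 0.32, and the proteoglycan Lum, by 1.14 ± 0.24.

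Of 25 markers of activated stellate cells and myofibroblasts, Acta2 and the protease inhibitor Timp3 (fell by 0.99 ± 0.20) were called, 23 were not, and 2 fell when adjusted over the list alone. The list's median was -0.79 (adjusted p = 2.17e-07, and adjusted p = 0.338 with an estimated correlation). Timp1 was at 4.77 ± 2.42 CPM against 11.7 ± 6.22 (log2 change -1.29 ± 0.54, adjusted p = 0.186, and -0.77 without TAA replicate 14, at 18.9 CPM against 7.98 and 8.27). Cthrc1, a collagen-associated secreted protein, fell from 2.37 ± 0.464 to 0.179 ± 0.075 CPM (adjusted p = 0.0379), near the floor, and the collagen crosslinking enzyme Loxl2 by 1.54 ± 0.24. Within the list of TGF beta signalling and targets, 3 of 22 genes fell and 19 were not called, with 3 falling when adjusted over the list alone. The median was -0.40 (adjusted p = 3.31e-06, and adjusted p = 0.130 with an estimated correlation), and the called members include Thbs1 and the activin subunit Inhba, which fell by 1.72 ± 0.35. Markers of quiescent stellate cells, 17 genes, had a median of -0.26 and no call (adjusted p = 0.958).

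**Figure D1:**
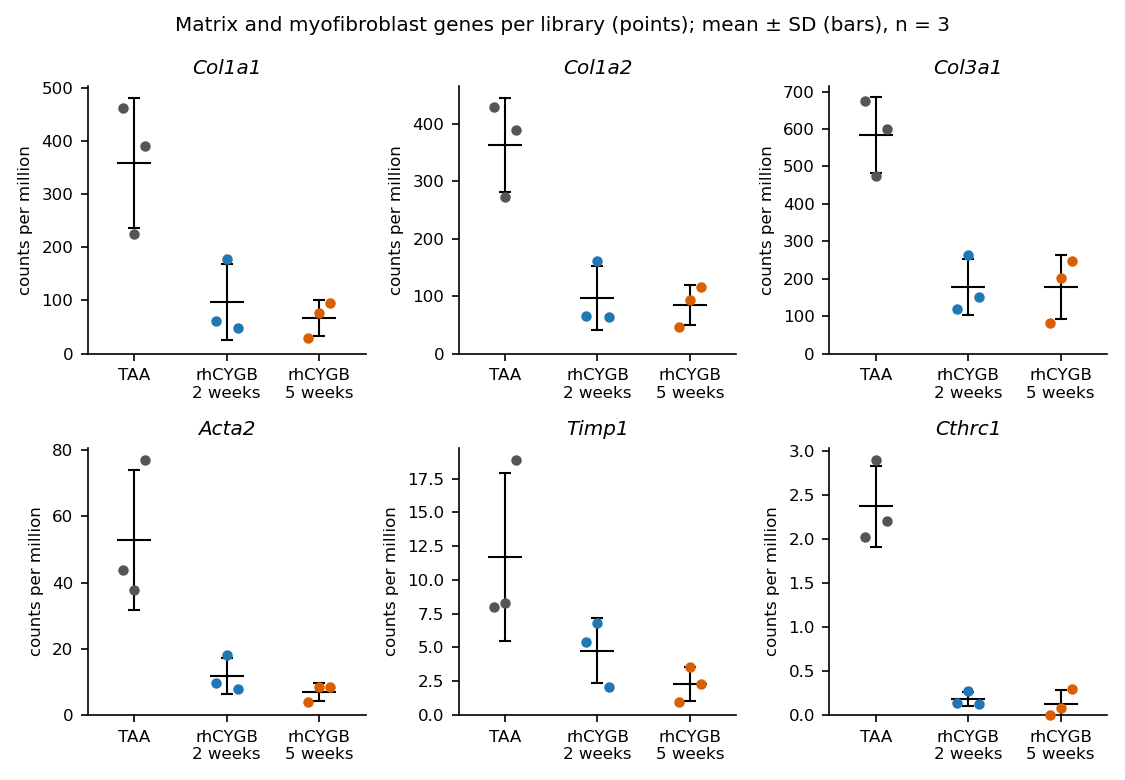
CPM (vertical axis, linear from 0) of 6 matrix and myofibroblast genes in each library (points), by group, with mean and SD (n = 3). Col1a2, Acta2 and Cthrc1 passed edgeR's test in both comparisons with TAA, and Col1a1, Col3a1 and Timp1 in neither. At 2 weeks the adjusted p was 0.0853 for Col1a1, 0.0507 for Col3a1 and 0.186 for Timp1. At 5 weeks it was 0.0669, 0.0669 and 0.0696 in that order.

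Genes of dividing cells gave the lowest list p by camera at the preset correlation, though not with an estimated correlation. Of 38 tested cell cycle genes 21 fell, 17 were not called and 36 fell when adjusted over the list alone, with a median of -0.84 (adjusted p = 3.22e-30, and adjusted p = 0.163 with an estimated correlation). The replication licensing factor Cdc6 fell by 1.71 ± 0.20, the topoisomerase Top2a by 1.04 ± 0.16 and the spindle protein Prc1 by 0.96 ± 0.16.

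Lists of immune cell markers ranked in opposite directions. Of 23 markers of infiltrating monocytes and macrophages 3 fell, 20 were not called and 5 fell when adjusted over the list alone (median -0.35, adjusted p = 3.56e-05, and adjusted p = 0.338 with an estimated correlation). Without 2-week replicate 17 that median was -0.22. The called genes are Gpnmb, a glycoprotein of lipid-laden macrophages, which fell by 1.70 ± 0.25, the elastase Mmp12, by 1.36 ± 0.17, and the chemokine receptor Cx3cr1, by 0.97 ± 0.21. Of 18 T and NK cell markers 4 rose, 14 were not called and 8 rose when adjusted over the list alone (median 1.25, adjusted p = 2.60e-09, and adjusted p = 0.217 with an estimated correlation). The chemokine Ccl5 rose 6.04-fold (12.1 ± 5.90 against 2.00 ± 0.42 CPM) and the granule protein Nkg7 4.66-fold. The CD8 chain Cd8b1 rose to 1.37 ± 0.572 CPM from 0.232 ± 0.016 CPM, and the granzyme Gzmk to 0.692 ± 0.091 CPM from 0.020 ± 0.034 CPM, all low levels. Cxcl9, a chemokine induced by interferon gamma, rose 4.21-fold. The list of interferon-stimulated genes ranked lower instead (median -0.40, camera adjusted p = 2.07e-05). It was not called in 2 of 17 alternatives, among them the estimated correlation.

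Metabolic lists ranked in both directions. Cholesterol biosynthesis ranked lower, with 0 of 24 genes called by edgeR or when adjusted over the list alone (median -0.52, camera adjusted p = 0.0031, and adjusted p = 0.583 with an estimated correlation), and lost its call without TAA replicate 12 or 2-week replicate 19. Fatty acid and triglyceride synthesis was not called (28 genes, median 0.19, adjusted p = 0.160).

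Several other metabolic lists ranked higher. Of 30 genes of cytochrome P450 metabolism 6 rose, 24 were not called and 13 rose when adjusted over the list alone (median 0.56, adjusted p = 2.32e-10, and adjusted p = 0.130 with an estimated correlation). Cyp2c38 rose 6.26-fold, Cyp2d10 2.28-fold and Cyp2c29 2.05-fold. Of 34 NRF2 targets, genes of the oxidative stress response, 9 rose, 25 were not called and 18 rose when adjusted over the list alone (median 0.49, adjusted p = 5.09e-11, and adjusted p = 0.217 with an estimated correlation), with the glutathione transferase Gstm1 2.69-fold higher, Gstm4 1.99-fold and Gstp1 1.67-fold. Fatty acid oxidation and ketogenesis had 9 of 32 genes higher, 23 not called and 14 higher when adjusted over the list alone (median 0.52, adjusted p = 5.03e-11, and adjusted p = 0.217 with an estimated correlation), led by the peroxisomal thiolases Acaa1b (2.40-fold) and Acaa1a (1.65-fold). Among 25 antioxidant enzymes 3 rose, 22 were not called and 12 rose when adjusted over the list alone (median 0.45, adjusted p = 3.98e-07, and adjusted p = 0.227 with an estimated correlation). Superoxide dismutases Sod1 and Sod2 rose 1.67-fold and 1.48-fold, while Gpx1 spanned 640 to 2186 CPM against 312 to 317 CPM in TAA (log2 change 1.91 ± 0.46, adjusted p = 0.0526, not called, and 1.12 without replicate 19).

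Of 30 genes of secreted proteins and hepatocyte identity 5 rose, 25 were not called and 12 rose when adjusted over the list alone (median 0.33, adjusted p = 1.44e-07, and adjusted p = 0.232 with an estimated correlation), such as coagulation factor F12 (1.66-fold) and the nuclear receptor Nr1i2 (1.81-fold). Its median was -0.01 when libraries were scaled by totals alone, and those of the acute phase (-0.02), phase II (-0.06), bile acid (-0.04), urea cycle (-0.04), pericentral (-0.01), periportal (-0.04) and globin (-0.13) lists also turned. The acute phase list had 3 of 29 genes higher, 26 not called and 5 higher when adjusted over the list alone (median 0.32, adjusted p = 2.21e-05, and adjusted p = 0.338 with an estimated correlation), with the orosomucoid Orm3 9.10-fold higher.

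Nuclear oxidative phosphorylation genes were 2 of 34 higher and 32 not called, and 30 were higher when adjusted over the list alone (median 0.56, adjusted p = 1.98e-13, and adjusted p = 0.217 with an estimated correlation). An example is Cox4i1, 1.61-fold. Of 38 ribosomal protein genes 0 were called by edgeR or when adjusted over the list alone (median 0.39, camera adjusted p = 1.69e-05, and adjusted p = 0.618 with an estimated correlation). These transcripts are short, with median lengths of 956 and 856 bases, and across genes, which are not independent replicates, the log2 change correlated with transcript length (rho -0.41). Replicates 17, 18 and 23 stood furthest apart on the first principal component (-39.4, -44.1 and 78.8, 32.3% of the variance).

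Other genes with large changes at 2 weeks were the antisense gene Hnf4aos (rose 4.79-fold, not separable from its partner without strand), the thyroxine carrier Serpina7 (rose by 2.36 ± 0.46, and by 1.60 without replicate 17, which had 98.9 CPM against 23.6 and 40.9), the sulfotransferase Sult2a7 (rose 6.61-fold), the matrix link protein Hapln1 (fell by 2.16 ± 0.21, adjusted p = 0.0089) and the AP-1 factor Fosl1 (fell by 2.16 ± 0.46). Adnp, a nuclear protein, passed the test with 0 to 0.15 CPM at 2 weeks against 17.7 to 25.0 CPM in TAA. At 5 weeks it was at 0 in replicate 27 against 26.3 and 30.8 CPM in 23 and 28. Levels also differed sharply within TAA for the ribosomal protein gene Rps27 (175, 133 and 2.35 CPM). For Lox, a member of the crosslinking list, they were 0.21, 10.4 and 10.9 CPM in TAA. The cause was not tested, so the Adnp change is not read as regulation.

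In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 488 of 14731 genes at 2 weeks, 291 up and 197 down (59.6% up). The share up was 45.1% with upper quartile scaling, 6.4% with library totals and 7.3% with log2(FPKM + 1). Groups did not overlap for 4958 genes (33.7%, against 10% by chance for a single gene). Genes vary together, also with transcript length, and no other split was scored for this share. An excess over the chance share is therefore not read as an effect, here or in the comparisons below. Camera called 28 of 53 lists, 17 up and 11 down. None of these had an adjusted p under 0.05 with an estimated correlation (10 of all 53 at an unadjusted p). Fry called 21, of which 19 are among the 28. The gene count was 31, 1 and 2 without TAA replicates 12, 13 and 14, 5 and 3 without 2-week replicates 17 and 18, and 1095, 888 and 169 without 5-week replicates 23, 27 and 28. It was 12 with 17, 18 and 23 all left out, a setting added after the data were seen. With trends over length and GC content removed, also added then, 679 genes were called, of which 340 are among the 488. No longer called there, with log2 changes after removal, are Gstp1 (0.29 ± 0.14), Sod1 (0.33 ± 0.11), Acaa1b (0.98 ± 0.24), Acaa1a (0.46 ± 0.16), Cox4i1 (0.19 ± 0.11), Thbs2 (-0.94 ± 0.24), Lum (-1.05 ± 0.28), Fbn1 (-1.24 ± 0.37), Timp3 (-0.77 ± 0.25) and Cx3cr1 (-0.80 ± 0.25). For Acaa1b, Thbs2, Lum, Fbn1, Timp3 and Cx3cr1 most of the change remained and the SE was larger, so the lost call does not show that bias made the change. The ribosomal list also lost its call (median 0.03).

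Comparing rhCYGB 5 weeks against TAA asks the same of a longer course. Acta2 fell by 2.93 ± 0.43 on the log2 scale (SE, n = 3 per group, adjusted p = 0.0361), from 52.8 ± 21.3 to 6.95 ± 2.71 CPM (SD). Col1a2 was 4.28-fold lower (adjusted p = 0.0495), at 85.0 ± 35.0 CPM. Cyp2e1, the P450 that activates thioacetamide (gene ID 13106, mm10 chromosome 7, 140763832 to 140774977), rose 2.60-fold, from 699 ± 206 to 1815 ± 321 CPM (log2 change 1.38 ± 0.21, adjusted p = 0.0361). Gys2, the liver glycogen synthase, rose 2.54-fold (adjusted p = 0.0361), Txnip, an inhibitor of thioredoxin that responds to glucose, 3.84-fold (adjusted p = 0.0379) and Cat, catalase, 1.63-fold (adjusted p = 0.0427). Arntl, a core factor of the circadian clock, fell by 1.12 ± 0.18 (adjusted p = 0.0361).

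Collagens were again lower, with 7 of 17 down, 10 not called, and 14 down and 1 up when adjusted over the list alone (median -1.20, adjusted p = 1.70e-16, and adjusted p = 0.133 with an estimated correlation). Col8a1 fell by 2.12 ± 0.34, Col5a1 by 1.73 ± 0.28, Col12a1 by 1.12 ± 0.19 and Col15a1 by 0.94 ± 0.14. Col1a1 was at 67.0 ± 33.9 CPM (log2 change -2.42 ± 0.57, adjusted p = 0.0669) and Col3a1 at 177 ± 85.7 CPM (-1.72 ± 0.40, adjusted p = 0.0669). Of 25 matrix glycoproteins 3 fell, 22 were not called and 9 fell when adjusted over the list alone (median -0.74, adjusted p = 5.33e-10, and adjusted p = 0.214 with an estimated correlation), with a median of -0.47 without 5-week replicate 23. They are Thbs1, which fell by 1.85 ± 0.32, tenascin Tnc, by 2.07 ± 0.41, and versican Vcan, by 1.56 ± 0.31. Myofibroblast markers had 1 of 25 genes down, Acta2, with 24 not called and 20 down when adjusted over the list alone (median -1.05, adjusted p = 5.46e-16, and adjusted p = 0.147 with an estimated correlation). Timp1 was at 2.29 ± 1.28 CPM (log2 change -2.36 ± 0.56, adjusted p = 0.0696). Beside these, markers of muscle from other tissue ranked lower, with 0 of 7 called by edgeR and 2 lower when adjusted over the list alone (median -1.86, camera adjusted p = 0.0011, and adjusted p = 0.218 with an estimated correlation). The muscle median was -1.16 without TAA replicate 14, and -1.35 at 2 weeks (adjusted p = 0.233, no call). Mesothelial and gallbladder markers also ranked lower, with 0 of 11 called by edgeR or when adjusted over the list alone (median -0.72, camera adjusted p = 0.0076, and adjusted p = 0.287 with an estimated correlation), and were not called in 6 of 17 alternatives, among them without TAA replicate 14 (median -0.29). Cholangiocyte and ductular markers ranked lower (0 of 19 called by edgeR or when adjusted over the list alone, median -0.58, camera adjusted p = 3.19e-04, and adjusted p = 0.412 with an estimated correlation). Their mean log2 CPM was 1.44 in replicate 23 against 3.03 and 2.97 in 27 and 28, and 2.95 to 3.63 in TAA. Markers of capillarised and vascular endothelium had 1 of 15 down, 14 not called and 2 down when adjusted over the list alone (median -0.33, adjusted p = 2.26e-04, and adjusted p = 0.246 with an estimated correlation).

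Cell cycle genes were 6 of 38 down, 32 not called and 31 down when adjusted over the list alone (median -0.66, adjusted p = 8.58e-22, and adjusted p = 0.133 with an estimated correlation). The mitotic kinase Plk1 fell by 1.03 ± 0.17, Prc1 by 1.02 ± 0.16, survivin Birc5 by 0.93 ± 0.16 and Cdc6 by 1.15 ± 0.20, and Mki67 had a log2 change of -0.76 ± 0.16 (adjusted p = 0.0521). Monocyte and macrophage markers had 2 of 23 genes down, 21 not called and 18 down when adjusted over the list alone (median -0.80, adjusted p = 1.35e-13, and adjusted p = 0.133 with an estimated correlation). These are Cx3cr1, which fell by 1.15 ± 0.22, and the chitinase-like protein Chil3, by 2.08 ± 0.38. The chemokine Ccl2 was at 3.82 ± 1.53 against 9.85 ± 2.52 CPM (log2 change -1.37 ± 0.33, adjusted p = 0.0707). Of 35 interferon-stimulated genes 1 fell, Oasl1 (by 1.18 ± 0.20), 34 were not called and 6 fell when adjusted over the list alone (median -0.53, adjusted p = 1.10e-09, and adjusted p = 0.246 with an estimated correlation). T and NK cell markers had 0 of 18 genes called by edgeR or when adjusted over the list alone (median 0.89, camera adjusted p = 0.000111, and adjusted p = 0.263 with an estimated correlation), and a median of 0.49 without 5-week replicate 27.

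Several metabolic lists ranked higher after 5 weeks, while cholesterol biosynthesis (24 genes, median -0.01, adjusted p = 0.501) and fatty acid and triglyceride synthesis (28 genes, median 0.12, adjusted p = 0.361) were not called. Phase II conjugation and transport had 2 of 29 genes up, 27 not called and 19 up when adjusted over the list alone (median 0.59, adjusted p = 9.84e-14, and an unadjusted p = 9.44e-04 with an estimated correlation, where the adjusted p was not under 0.05), with the glucuronosyltransferases Ugt2b36 1.56-fold and Ugt1a6a 1.70-fold higher. Of 30 cytochrome P450 genes 4 rose, 26 were not called and 16 rose when adjusted over the list alone (median 0.58, adjusted p = 1.52e-11, and adjusted p = 0.0820 with an estimated correlation), among them Cyp2d9 (1.87-fold) and Cyp2f2 (1.64-fold). Fatty acid oxidation and ketogenesis had 4 of 32 genes up, 28 not called and 22 up when adjusted over the list alone (median 0.47, adjusted p = 2.05e-15, and adjusted p = 0.142 with an estimated correlation), including Acaa1b (2.05-fold) and Acaa1a (1.59-fold). Gluconeogenesis and glycogen genes were 4 of 19 up, 15 not called and 10 up when adjusted over the list alone (median 0.50, adjusted p = 1.08e-08, and adjusted p = 0.133 with an estimated correlation). They are Gys2, the glucose transporter Slc2a2 (2.17-fold), Ugp2 (1.66-fold) and the pyruvate kinase Pklr (2.01-fold). Bile acid genes had 1 of 25 up, Slc27a5 (1.70-fold), 24 not called and 11 up when adjusted over the list alone (median 0.58, adjusted p = 6.63e-09, and adjusted p = 0.116 with an estimated correlation). The bile acid median was 0.38 without 5-week replicate 23.

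Male-biased liver genes had 2 of 25 members up, 23 not called and 15 up when adjusted over the list alone (median 0.75, adjusted p = 3.19e-12, and adjusted p = 0.218 with an estimated correlation), and Cyp4a12b rose 6.27-fold. Replicate 23 stood apart here: the list's mean log2 CPM was 7.72 in it against 6.39 and 6.54 in 27 and 28 (TAA 5.82 to 6.17), Cyp4a12b was at 198.1 CPM against 48.2 and 81.7, and without it the log2 change of Cyp4a12b went from 2.65 to 1.88 and the list median was 0.48, still called. Clock genes were 1 of 20 up, 2 down and 17 not called, and 11 were up and 2 down when adjusted over the list alone (median 0.64, adjusted p = 0.000606, and adjusted p = 0.246 with an estimated correlation). The called members include Arntl and its relative Npas2, which fell by 2.01 ± 0.39. Saa3 rose 22.8-fold (adjusted p = 0.0406), to 128 ± 97.9 CPM (log2 change 4.51 ± 0.78, and 3.72 without replicate 27), and Areg, an EGF receptor ligand, fell by 2.66 ± 0.42. The red-cell carbonic anhydrase Car1 rose 3.02-fold, the steroid dehydrogenase Hsd17b6 2.63-fold and the aldehyde dehydrogenase Aldh3a2 2.57-fold, while the neutrophil protease Prtn3 fell by 2.90 ± 0.47 and the aggrecanase Adamts4 by 2.35 ± 0.36.

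**Figure D2:**
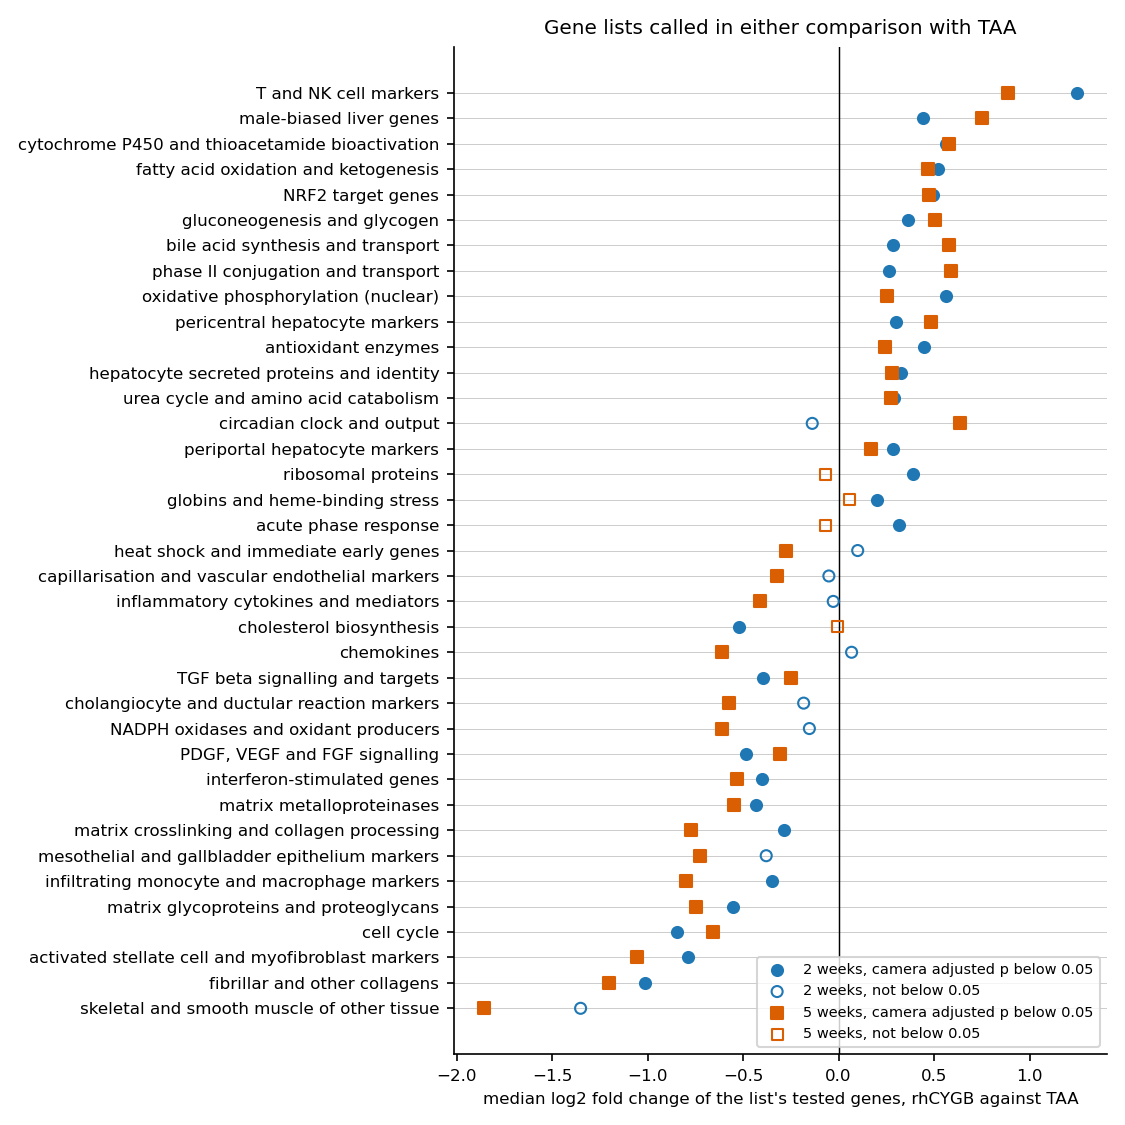
Median log2 fold change (horizontal axis) of each gene list called by camera in either comparison with TAA, at 2 weeks (circles) and 5 weeks (squares), filled where the camera adjusted p is under 0.05. The collagens sit at -1.02 and -1.20, the cell cycle genes at -0.84 and -0.66, and the cytochrome P450 genes at 0.56 and 0.58, all relative to TMM scaling, while some hepatocyte lists turn negative when scaled by totals.

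At 5 weeks edgeR called 190 of 14731 genes, 101 up and 89 down (53.2% up), with a share up of 41.6% under upper quartile scaling, 7.5% under library totals and 6.9% with log2(FPKM + 1). Groups did not overlap for 3679 genes (25.0%, against 10% by chance for a single gene). Camera called 33 of 53 lists, 15 up and 18 down. None of these had an adjusted p under 0.05 with an estimated correlation (14 of all 53 at an unadjusted p). Fry called 22, all among the 33. The lowest adjusted p was 0.0361, and the gene count was 5 and 2 without TAA replicate 12 and 5-week replicate 28. It was 0 without any of TAA replicates 13 and 14, 2-week replicates 17, 18 and 19 or 5-week replicate 23 (1890 to 2855 genes at an unadjusted p under 0.05), against 1188 by DESeq2 and 1954 by limma voom on all libraries. The count was 1 when only the 6 libraries compared were fitted and 7 without 17, 18 and 23 together, the latter added after the data were seen, and the periportal list's median of 0.17 turned to -0.05 under library totals.

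Both courses against the same TAA livers can be set side by side. Of the 488 and 190 calls, 96 genes were shared, 46 higher and 50 lower in both, with 0 in opposite directions. Shared calls named above include Acta2, Col1a2, Col8a1, Col5a1, Thbs1, Loxl2, Cthrc1, Cdc6 and Prc1, all lower, and Saa3, Acaa1b, Acaa1a, Sult2a7 and Hnf4aos, all higher. Independent lists of these sizes would share 2.00 genes up and 1.19 down, a count that leaves the common controls out of account. In 20 simulations of unchanged groups with common controls, at most 2 and 1 genes were called, so the shared count there (mean 0.050) could only be near 0 and is no measure for 96. Over all genes the log2 changes correlated at r = 0.499 (simulated 0.496, 0.456 to 0.526) and the covariance was 0.176 (simulated 0.070, 0.063 to 0.077), a difference of 0.105. Among genes with a mean of at least 10 CPM it was 0.060, for which no simulation was made. Genes of equal sign went the other way, at 62.4% against 66.5% simulated (65.9% to 67.3%). Part of the covariance and of the shared calls may come from the shared controls, since 3 TAA libraries are too few to split. The simulations drew genes independently and held no trend over length or GC content. Such a trend in the TAA libraries would enter both comparisons. The covariance above the simulated one is therefore not read as going beyond the shared controls. The shared count was 3 without TAA replicate 12, 84 without 5-week replicate 27, and 0 without any other single library. It was 3 with 17, 18 and 23 left out together.

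**Figure D3:**
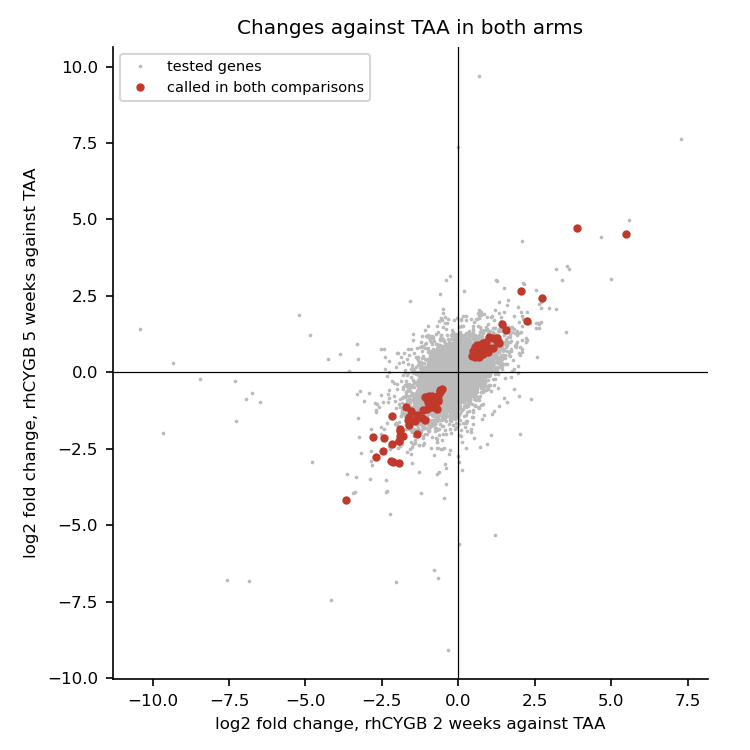
Log2 fold change of each tested gene at 2 weeks (horizontal axis) and 5 weeks (vertical axis) of rhCYGB against the same TAA libraries, with the 96 genes called in both comparisons in red. All 96 lie in the quadrants of equal sign, and shared controls alone give a correlation near the observed 0.499.

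Comparing rhCYGB 5 weeks against rhCYGB 2 weeks tests directly whether the courses differ. Mcm10, a DNA replication initiation factor (gene ID 70024, mm10 chromosome 2, 4990724 to 5012791), was 4.96-fold higher after 5 weeks (log2 change 2.31 ± 0.20, SE, n = 3 per group, adjusted p = 0.0084), at 41.9 to 65.4 CPM against 9.40 to 12.6 CPM. In TAA livers Mcm10 was at 27.2 to 38.1 CPM. Abcd2, a peroxisomal fatty acid transporter, was 2.35-fold higher (log2 change 1.23 ± 0.13, adjusted p = 0.0171). It was at 15.99 to 18.85 CPM after 5 weeks and 6.83 to 7.69 CPM after 2 weeks. Both lay below TAA, at 21.06 to 25.85 CPM. Tjp3, a tight junction protein, was lower by a log2 change of -1.09 ± 0.12 (adjusted p = 0.0171). Its levels were 18.09 to 22.61 CPM after 5 weeks, 41.41 to 45.61 CPM after 2 weeks and 28.10 to 29.09 CPM in TAA. With trends over length and GC content removed, Mcm10 kept its call (2.09 ± 0.14, adjusted p = 9.97e-04), while Abcd2 (0.79 ± 0.17) and Tjp3 (-0.85 ± 0.11) lost theirs. Collagen genes were not called between the courses, with 0 of 17 called by edgeR or when adjusted over the list alone (median -0.12, camera adjusted p = 0.324).

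Among lists, ribosomal protein genes ranked lower after 5 weeks (0 of 38 called by edgeR or when adjusted over the list alone, median -0.49, camera adjusted p = 1.51e-08, and adjusted p = 0.775 with an estimated correlation), and across genes the log2 change correlated with transcript length (rho 0.47). Without 5-week replicate 23 the ribosomal median was -0.28 and that of the clock genes 0.30, both still called. Acute phase genes ranked lower, with 0 of 29 called and 4 lower when adjusted over the list alone (median -0.40, adjusted p = 5.81e-05, and adjusted p = 0.771 with an estimated correlation). Clock genes ranked higher, with 0 of 20 called, and 9 higher and 4 lower when adjusted over the list alone (median 0.49, adjusted p = 0.0031, and adjusted p = 0.771 with an estimated correlation). Values of uncalled members are a log2 change of -1.37 ± 0.18 for Arntl (adjusted p = 0.0645) and 1.73 ± 0.28 for the period gene Per3 (adjusted p = 0.109), at 31.6 ± 6.82 against 9.53 ± 2.74 CPM. Gys2 had a log2 change of 1.00 ± 0.16 (adjusted p = 0.109), Golim4, a Golgi protein, 2.62 ± 0.36 (adjusted p = 0.0645), and Sdf2l1, an endoplasmic reticulum chaperone cofactor, -0.85 ± 0.12 (adjusted p = 0.0645).

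**Figure D4:**
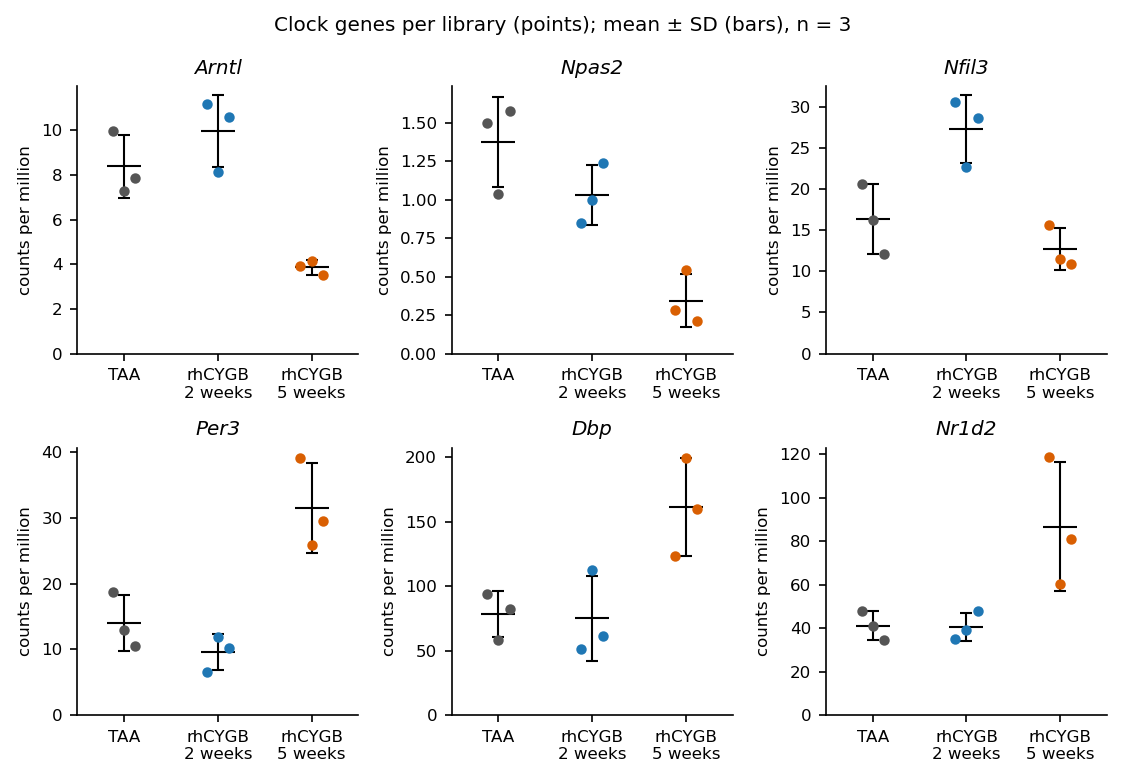
CPM (vertical axis, linear from 0) of 6 clock genes in each library (points), by group, with mean and SD (n = 3), the genes beyond Arntl, Npas2 and Per3 picked after their values were seen. Arntl lies at 3.50 to 4.15 CPM in the 5-week libraries and at 7.29 to 11.2 CPM in the other 6. Clock, Per1 and Nr1d1, not shown, had log2 changes of 0.60 ± 0.53, 0.11 ± 0.37 and -0.04 ± 0.19 (SE) between the courses. They did not clearly move with the genes of their phase, while Cry1, Tef, Hlf, Per2, Bhlhe41 and Ciart, also not shown, did.

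In this comparison edgeR called 3 of 14731 genes, 2 up and 1 down, with 3421 at an unadjusted p under 0.05, 788 called by DESeq2 and 3978 by limma voom. Groups did not overlap for 3108 genes (21.1%, against 10% by chance for a single gene). Camera called 16 of 53 lists, 5 up and 11 down. None of these had an adjusted p under 0.05 with an estimated correlation (1 at an unadjusted p) or by fry (11 at an unadjusted p). The gene count was 1889 without 5-week replicate 27, 11 without 2-week replicate 19, and 1, which is among the 3, without any of TAA replicates 12, 13 and 14 or 5-week replicate 23. Without 2-week replicate 17 or 18 it was also 1, but none of Mcm10, Abcd2 and Tjp3 was called. The count was 0 when only the 6 libraries compared were fitted (2451 at an unadjusted p under 0.05), and 5, none of them among the 3, with 17, 18 and 23 left out together, which was added after the data were seen.

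Pooling both courses, any rhCYGB against TAA compares 6 libraries with 3. Col1a1 (gene ID 12842, mm10 chromosome 11, 94936224 to 94953042) fell by 2.14 ± 0.45 on the log2 scale (SE, adjusted p = 0.0432), from 359 ± 122 CPM (SD, n = 3) to 81.6 ± 52.7 CPM (SD, n = 6). Col1a2 fell by 2.00 ± 0.33 (adjusted p = 0.0247), Col3a1 by 1.72 ± 0.32 (adjusted p = 0.0317) and Acta2 by 2.49 ± 0.38 (adjusted p = 0.0211). Mki67 fell by 0.87 ± 0.14 (adjusted p = 0.0245). The antioxidant enzymes Sod2 and Cat rose 1.46-fold (adjusted p = 0.0312) and 1.51-fold (adjusted p = 0.0471). Cyp2e1 was at 1491 ± 410 CPM against 699 ± 206 (log2 change 1.09 ± 0.26, adjusted p = 0.0574), and Timp1 at 3.53 ± 2.20 against 11.7 ± 6.22 (-1.73 ± 0.51, adjusted p = 0.105), so neither was called.

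Collagens were 10 of 17 down, 7 not called, and 14 down and 2 up when adjusted over the list alone (median -1.11, adjusted p = 1.53e-21, and adjusted p = 0.0690 with an estimated correlation), with Col5a2 down by 1.92 ± 0.28 among them. Myofibroblast markers had 1 of 25 down, 24 not called and 20 down when adjusted over the list alone (median -0.85, adjusted p = 1.59e-15, and adjusted p = 0.130 with an estimated correlation). Cell cycle genes were 17 of 38 down, 21 not called and 34 down when adjusted over the list alone (median -0.75, adjusted p = 5.65e-35, and adjusted p = 0.0623 with an estimated correlation). The cytochrome P450 list, 4 of 30 genes up, 26 not called and 16 up when adjusted over the list alone (median 0.59, adjusted p = 7.60e-13), also passed with an estimated correlation (adjusted p = 0.0367). Its members include Cyp2a5, which rose 3.81-fold to 3425 ± 1288 CPM, and Cyp2c38, which rose 4.64-fold. Cholangiocyte and ductular markers also ranked lower, with 1 of 19 down, 18 not called and 1 down when adjusted over the list alone (median -0.37, adjusted p = 0.0034, and adjusted p = 0.495 with an estimated correlation), and were not called without TAA replicate 14 (median -0.10). Markers of capillarised and vascular endothelium had 1 of 15 down, 14 not called and 1 down when adjusted over the list alone (median -0.18, adjusted p = 0.0018, and adjusted p = 0.285 with an estimated correlation). Lists of other cell types that were not called include the sinusoidal endothelial list (20 genes, 0 called by edgeR, median -0.10, camera adjusted p = 0.414) and the Kupffer cell list (14 genes, 0 called, median 0.25, adjusted p = 0.0595). T and NK markers ranked higher, with 0 of 18 called and 7 higher when adjusted over the list alone (median 1.07, adjusted p = 3.36e-08, and adjusted p = 0.142 with an estimated correlation). Replicate 23 did not share this: its mean log2 CPM over the list was -1.27, within the TAA range of -1.49 to -1.07, against -0.54 to 0.31 in the other 5 rhCYGB libraries.

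EdgeR called 295 genes for any rhCYGB, 128 up and 167 down (43.4% up), with a share up of 26.7% under upper quartile scaling, 5.0% under library totals and 5.1% with log2(FPKM + 1). Groups did not overlap for 1797 genes (12.2%, against 2.38% by chance for a single gene). Camera called 30 of 53 lists, 16 up and 14 down. Of these 1, the cytochrome P450 list, was called with an estimated correlation (17 of all 53 at an unadjusted p). Fry called 24, of which 23 are among the 30. The gene count was 129, 79, 41 and 180 without replicates 17, 19, 27 and 28, and 620 without replicate 23. It was 0 without any of TAA replicates 12, 13 and 14 (1741 to 2023 genes at an unadjusted p under 0.05), against 1230 by DESeq2 and 1591 by limma voom on all libraries. The medians of the acute phase (-0.15), urea cycle (-0.01), periportal (-0.07) and glucocorticoid (-0.06) lists turned negative under library totals.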

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

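The 5-week and 2-week groups were compared directly by edgeR for genes and camera for lists, and what passed is given here because it differs between the groups. Of the explanations below, length and GC bias had its prediction written before its result was seen. Time of day, dilution by hepatocytes and loss of stellate cells were chosen after the results were seen.

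Collagens, myofibroblast markers and cell cycle genes were lower in any rhCYGB against TAA, and with trends over length and GC content removed the differences in mean log2 CPM stayed at -1.08 ± 0.20, -1.16 ± 0.26 and -0.72 ± 0.07 (SE), which excludes that bias as the whole cause. A higher share of hepatocytes would lower all other cell types alike, but the falls exceeded the changes of Kupffer, sinusoidal and T and NK cell markers by at least -1.09 ± 0.21, -1.06 ± 0.33 and -0.66 ± 0.12. An equal dilution of all other cell types is thus excluded as the whole cause. These 3 cell types were chosen after the results were seen. Other lists did go the way dilution predicts, by less than the collagens: monocytes and macrophages (median -0.54), cholangiocytes (-0.37) and capillarised endothelium (-0.18), so a part played by it stays open. Mean log2 CPM of the monocyte list was 3.98 to 4.30 in TAA and 3.02 to 3.79 after rhCYGB. That of the cell cycle genes was 3.99 to 4.09 and 2.90 to 3.46, so their margin depends on which cell types are compared. Fewer stellate cells of every state would lower myofibroblast and quiescent stellate markers alike. Myofibroblast markers fell beyond the quiescent markers by -1.08 ± 0.28, and the quiescent markers changed by -0.06 ± 0.17. The contrast cannot decide this, as carry-over of other muscle, not excluded below, could also lower smooth muscle genes such as Acta2. A loss of stellate cells of every state is therefore not excluded. A biological effect of rhCYGB is possible, but it was not tested against every other cause, and 3 TAA libraries serve both courses. The labels give no batch, cage or collection day, so such differences between the groups cannot be told from rhCYGB. Muscle markers of other tissue also ranked lower (median -1.46, camera adjusted p = 0.0051, and adjusted p = 0.239 with an estimated correlation, not called without TAA replicate 14). Carry-over of such tissue in TAA samples was therefore not excluded.

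Ribosomal protein and oxidative phosphorylation genes, which are short, differed between groups whose libraries also differ in their trends over length. For ribosomal proteins at 2 weeks against TAA the difference went from 0.32 ± 0.20 to -0.02 ± 0.12 once the trends were removed, and at 5 weeks against 2 weeks from -0.53 ± 0.30 to -0.18 ± 0.14. For oxidative phosphorylation at 2 weeks it went from 0.51 ± 0.09 to 0.24 ± 0.03. Bias between libraries may thus account for the ribosomal differences and for part of the other. Removal would also take out a biological shift that follows length, so a biological cause is not excluded.

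Clock genes differed between 5 weeks and 2 weeks. With length and GC trends removed the difference between the opposite phases was 1.89 ± 0.37, against 1.82 ± 0.39 before, which excludes that bias. A different time of day at collection predicts that genes peaking with Arntl and those of the opposite phase move apart, and they did, by 1.82, with changes of -0.77 ± 0.23 and 1.05 ± 0.21. An effect of the longer course on the clock predicts the same, so these data cannot separate the explanations, and collection times are not given. Against TAA, genes peaking with Arntl and those of the opposite phase changed by -0.69 ± 0.18 and 0.77 ± 0.15 at 5 weeks. At 2 weeks against TAA the changes were 0.07 ± 0.24 and -0.29 ± 0.21. A different collection time could thus also bear on other genes at 5 weeks against TAA, which was not tested.

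Between 5 and 2 weeks the log2 change was 2.31 for Mcm10, 1.23 for Abcd2 and -1.09 for Tjp3. Only Mcm10 kept its call with length and GC trends removed, although most of the change of Abcd2 and Tjp3 remained. The list medians that passed camera were -0.49 for ribosomal proteins, -0.40 for the acute phase, -0.19 for endoplasmic reticulum stress, -0.32 for oxidative phosphorylation and -0.76 for chemokines. Others were 0.49 for the clock, 0.24 for phase II genes, -0.56 for T and NK cells, 0.21 for the cell cycle and -0.32 for heat shock and immediate early genes. The rest were -0.39 for matrix crosslinking, -0.29 for monocytes and macrophages, -0.31 for antioxidant enzymes, 0.31 for cholesterol synthesis, 0.56 for male-biased genes and -0.29 for myofibroblast markers. None of these lists passed with an estimated correlation (adjusted p of 0.771 or more). Over 17 alternatives the T and NK median ran from -0.96 to -0.08 and that of phase II genes from 0.03 to 0.35. Without 5-week replicate 23, 9 of the 16 lists kept their call. Among those that lost it, the male-biased list turned (median 0.038, camera adjusted p = 0.902). The crosslinking, monocyte, antioxidant, cholesterol, cell cycle, male-biased and myofibroblast lists were not called in 6 to 8 of 17 alternatives each.

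In Dixon's test among the 6 rhCYGB libraries, 2 of 30 genes had a library far from the others, where chance gives about 1 in 20. Cyp4a12b was at 198.1 CPM in replicate 23 (others 45.7 to 101.5) and Mki67 at 21.7 CPM in replicate 17 (others 30.6 to 35.8).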

How the results depend on the processing

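Removal of length and GC trends and leaving out 17, 18 and 23 together were chosen after the results were seen, and the latter leaves 1 library at 2 weeks, assumed to vary like the other groups. The 2 settings chosen for TPM were not run, as the tables hold no TPM. Called genes picked for naming, a few of which the text leaves out, gave 3401 values over 148 results: 2152 kept their call, 1249 lost it and 0 reversed, mostly with a library left out. Genes picked though not called kept that in 460 of 552. Called lists gave 1817 values, of which 1579 kept the call, 235 lost it (106 with an estimated correlation) and 3 reversed. Lower depth was not simulated, so what depth limits was not measured beyond the count filter of 14731 of 24532 genes.

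In the order 2 weeks against TAA, 5 weeks against TAA, 5 weeks against 2 weeks and any rhCYGB, edgeR called 488, 190, 3 and 295 genes. DESeq2 gave 1713, 1188, 788 and 1230, limma voom 2550, 1954, 3978 and 1591, and log2(FPKM + 1) 1983, 1001, 5 and 1641. Library totals gave 1722, 504 and 1163 for the comparisons with TAA, upper quartile 77 and no filter 105 at 5 weeks. Only the 6 libraries compared gave 1023, 1 and 0, the mean of both rhCYGB groups in the 3-group fit 571. Trends removed gave 679 (340 of them among the 488), 855, 4 (1 of the 3) and 924. With 17, 18 and 23 out the first 3 counts were 12, 7 and 5. By construction, an adjusted p under 0.1 gave 1439, 740, 10 and 810, and a 2-fold change as well as an adjusted p gave 187, 97 and 117 for those with TAA. An unadjusted p with 2-fold gave 618, 494 and 445 in the last 3. Without one library the counts ran 1 to 1095, 0 to 240, 1 to 1889 and 0 to 620. For the rest the cause was not tested.

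Lists called were 28, 33, 16 and 30. An estimated correlation left 0, 0, 0 and 1, fry left 0 at 5 weeks against 2 weeks, and voom 10 there. Without one library they ran 27 to 33, 33 to 36, 10 to 26 and 31 to 35. Shared calls, 96, were 60 at a mean of at least 10 CPM (fewer genes), 305 with library totals, 307 with trends removed and 3 with 17, 18 and 23 out, and ran 0 to 84 without one library. The correlation of 0.499 was 0.380 at 10 CPM and 0.351 to 0.570 without one library. The covariance of 0.176 was 0.060 at 10 CPM, 0.347 with 17, 18 and 23 out, and 0.167 to 0.275 without one library. In 5 weeks against 2 weeks, camera turned the direction of 3 lists, with medians of 0.038 for male-biased genes without 5-week replicate 23 (up to 0.727 without another library), 0.009 for oxidative phosphorylation with trends removed and 0.161 for myofibroblast markers with 17, 18 and 23 out. The medians of antioxidant enzymes (0.061, trends removed) and ribosomal proteins (0.022, 17, 18 and 23 out) also turned, with no call. The cause was not tested.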

Other observations

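In any rhCYGB against TAA, interferon-stimulated genes ranked lower, with 2 of 35 down, 33 not called, and 15 down and 1 up when adjusted over the list alone (median -0.47, adjusted p = 8.26e-10, and adjusted p = 0.177 with an estimated correlation). Monocyte and macrophage markers had 3 of 23 down, 20 not called and 8 down when adjusted over the list alone (median -0.54, adjusted p = 1.69e-10, and adjusted p = 0.137 with an estimated correlation), with Cx3cr1 down by 1.05 ± 0.18. Lists with no gene called by edgeR and no camera call include p53 targets (28 genes, median 0.06, adjusted p = 0.843), apoptosis and necroptosis effectors (24 genes, median 0.05, adjusted p = 0.560) and neutrophil markers (14 genes, median -0.48, adjusted p = 0.576). Sex is not given on the labels, and the Y-linked genes Eif2s3y and Uty had reads in all 9 libraries.

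Libraries differed in their trends over transcript length (rho across genes with each gene's mean): 0.19, 0.37 and -0.07 in TAA replicates 12, 13 and 14, -0.44, -0.41 and -0.20 in 17, 18 and 19 at 2 weeks, and 0.42, -0.37 and 0.32 in 23, 27 and 28 at 5 weeks. Over GC content the values were -0.00, -0.22 and 0.10, then 0.32, 0.46 and -0.02, then -0.36, 0.06 and -0.29. The second principal component held TAA at 38.0 to 41.1 and rhCYGB at -40.6 to 1.1.

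Every other split of the same libraries was tested, with predictions written before the results were seen. For any rhCYGB, 1 of 84 splits, the real one, gave as many called genes (295, highest other 7), a share under the preset 0.05. This makes a chance split unlikely without excluding it. Mixed splits carry the real difference as spread within groups, which lowers their calls. The splits also cannot tell rhCYGB from other differences between the groups. For lists, 12 of 84 splits gave as many calls (30, highest other 36), so for the count of lists chance is not excluded. With 3 against 3 there are 10 splits, too few for a share under 0.05. There the real gene counts were 488 at 2 weeks against TAA (highest other 2, 1 split with as many), 190 at 5 weeks against TAA (2, 1 split) and 3 between courses (2, 1 split). The list counts were 28 (highest other 30, 2 splits), 33 (31, 1 split) and 16 (24, 7 splits).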
